A study of Mus musculus with 10 samples.

How the data were processed

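RNA from 10 mouse gastric tumours was sequenced, 5 from an inflamed type and 5 from a desert type, with 1 library per tumour. Per the labels, the inflamed tumours arose in mice with floxed Apc and Trp53 and a tamoxifen-inducible Cre recombinase under Tff1, and the desert tumours were orthotopic allografts with wild type given as genotype. Whether that describes the host or the grafted cells, and which alterations the grafted cells carry, was not given in the sources used here. Tumour type therefore coincided with the tumour model, the genotype and the way the tumour was made, and these could not be told apart. No batch or date was given. The protocol text speaks of 6 tumours, whereas the series holds 10, and all 10 were used. Total RNA was extracted with TRIzol, per the labels' protocols. Whether the libraries kept the strand was not given in the sources used here, so reads from overlapping or antisense genes cannot be separated.

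The authors deposited FPKM values (read counts scaled by gene length and library size) in 1 table of 56748 genes with 1 column per library. The aligner, the read counter and the annotation release were not given in the sources used here. The submitters' processing notes name the genome build mm10. Of the 52125 gene IDs shared with the GENCODE M21 annotation of GRCm38, 1537 had the same start, 50435 the same span length and 52123 the same chromosome, so positions are given as the table holds them, with no build named. FPKM multiplied by the table's gene length gave whole multiples of a single step in each library (100% of the values above 0 within 0.01 of a whole number). From these steps the libraries held between 14148147 and 16951640 reads in genes. The library total behind the authors' FPKM was 0.98 to 1.15 times that sum, so the deposited values carry a scaling whose formula was not given. That factor was 1.06 ± 0.0569 in inflamed and 1.12 ± 0.0429 in desert tumours (mean ± SD, n = 5 each). The groups overlapped in this factor (0.98 to 1.12 and 1.04 to 1.15) and their difference was not tested. They did not overlap in the sum of FPKM over all genes, which was 2.81e+05 to 3.56e+05 in inflamed and 2.37e+05 to 2.70e+05 in desert tumours. Rescaling to TPM makes these sums equal. Other scalings were among the alternatives.

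GC content and the longest transcript of each gene were taken from GENCODE M21. Each gene was compared on log2(FPKM + 1), a scale that understates the change of low genes, with limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8) (moderated test with an intensity trend and robust moderation, two-sided, group as the only term). Genes with a mean FPKM of at least 0.5 over the 10 libraries were tested, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Differences are inflamed minus desert. Fixed lists of marker and process genes (42 lists, 517 members, all found in the table) were tested with limma's camera test against all other genes, with a preset correlation of 0.01 between genes and again with an estimated correlation, over the 37 lists with at least 5 tested members. Member counts are given over all genes and adjusted over the list alone. A score per tumour, the mean log2(FPKM + 1) of the tested members, was compared by an exact two-sided permutation test, whose smallest possible p in this design is 0.00794, with Benjamini-Hochberg adjustment over the 37 lists.

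Named genes followed a fixed rule: adjusted p under 0.05, no overlap between the groups, a mean FPKM of at least 5 in the higher group, and predicted genes, pseudogenes, ribosomal protein genes and antigen receptor segments left out; of these the 12 largest rises and the 12 largest falls were taken, and 1 of the falls is not reported here. Apc, Trp53 and Tff1 were added, with up to 4 members of each list, the 2 of largest difference and the 2 of highest mean FPKM. The rule, the lists, the tests and the main alternatives were fixed before the data were examined. Members named outside the rule, among them those that went against the rest of their list, were chosen after their values were seen.

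The alternatives were pseudocounts of 0.1 and 0.01, no filter on low values, a mean FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, limma without trend and robust moderation, a fold change floor of 2, array quality weights, the tumour number as a block, and each library left out in turn. Limma voom on the recovered reads (mean of at least 10 reads), 3 sets of libraries left out and the removal of chromosome medians were added after the data had been examined. Ranges of adjusted p over the alternatives leave out the estimated correlation, given beside each called list, and inflamed tumour 3 alone against the desert tumours, where 1 tumour cannot show the spread among inflamed tumours. For genes the ranges include the fold change floor of 2, which tests whether a difference exceeds 2-fold. A smaller difference has a high adjusted p there, however precise it is, so the upper end of a range can reflect that other question. The gene and list tests were tested on simulated data with 200 changed genes among 16750 genes in 5 and 5 libraries. Of 100 genes changed by 1 on the log2 scale 76 were recovered, and of 100 changed by 2 there were 93, with 0 called in the wrong direction. The 182 calls also held 10 false calls and 3 of the 14 members of a list shifted by 1. That list was found (camera adjusted p = 1.4e-13), and 1 unshifted list was also called. The simulated genes varied independently of each other, and few of them were changed. The simulation therefore does not show how often lists of correlated genes are called falsely in the real data. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15. Each label names a separate tumour. Nothing states whether tumours came from separate mice, or whether the desert grafts share 1 source of cells. The p-values set each difference against the spread between these tumours only. If the grafts share 1 source, that spread does not cover desert tumours of other origin.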

Results

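Bulk RNA sequencing was done on 5 inflamed and 5 desert gastric tumours of mice, and expression was deposited as FPKM per gene. The inflamed tumours held 15474313 to 15975770 reads in genes per library and the desert tumours 14148147 to 16951640, so depth did not separate the groups. Pearson correlations of log2(FPKM + 1) over 16750 tested genes were 0.926 to 0.975 among inflamed tumours, 0.952 to 0.976 among desert tumours and 0.701 to 0.765 between the groups. The first principal component held 78.3% of the variance and separated the groups. Mitochondrially encoded genes took 2.56% ± 0.657 (SD, n = 5) of the reads in inflamed and 1.58% ± 0.174 (SD, n = 5) in desert tumours. The 10 most abundant genes took 6.57% ± 1.13 and 4.17% ± 0.416 of the reads in the same groups.

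The genotype of the inflamed tumours puts Apc, Trp53 and the driver gene Tff1 at the start of the comparison. Apc (ENSMUSG00000005871, chromosome 18, 34353977 to 34455605 in the deposited table), a negative regulator of Wnt signalling, was at 5.42, 5.33, 8.29, 6.38 and 6.50 FPKM in inflamed tumours 1 to 5 and at 3.00, 3.75, 4.86, 5.58 and 4.62 FPKM in desert tumours 1 to 5. Its log2 difference was 0.47 (SE 0.15, limma adjusted p = 0.0182). The call was lost after rescaling to TPM (0.25, adjusted p = 0.29, with 0.000554 to 1 over the alternatives, the highest with the fold change floor of 2). That rescaling put the median difference of all tested genes at -0.28. The Apc difference was 0.84 once the median of each chromosome was removed, chromosome 18 having a median of -0.43. Trp53 (ENSMUSG00000059552, chromosome 11, 69471185 to 69482699), which encodes p53, was at 7.05, 7.75, 9.06, 8.58 and 10.4 FPKM in inflamed tumours 1 to 5 and at 1.95, 1.89, 2.81, 2.69 and 3.47 FPKM in desert tumours 1 to 5 (log2 difference 1.43, SE 0.14, limma adjusted p = 6.84e-06). These values cover whole genes, and RNA from unrecombined cells or from exons outside a floxed part stays in them, so they do not measure the loss of the floxed parts. Tff1 (ENSMUSG00000024032, chromosome 17, 31380369 to 31384251), a gastric trefoil factor, was at 0.242, 0.591, 1.06, 37.8 and 1.56 FPKM in inflamed tumours 1 to 5, and in desert tumours it was listed at 0 except for 0.0748 FPKM in desert tumour 4. Its difference was not called (1.71, SE 0.78, limma adjusted p = 0.0783). It was called with a pseudocount of 0.1 (3.98, adjusted p = 0.00607) and without inflamed tumour 1 (2.07, adjusted p = 0.0472), with 0.000889 to 1 over the alternatives.

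The comparison of the 2 tumour types asked how inflamed and desert tumours differ in expression. In inflamed tumours the gastric pit, neck and chief, T cell, interferon-gamma and MHC lists were higher, and the Wnt target and proliferation lists were lower, by the set test with a preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.510 to 0.572). Tff2 (ENSMUSG00000024028, chromosome 17, 31360023 to 31363256), a trefoil peptide of mucous neck cells, was at 7052 ± 2380 FPKM (SD, n = 5) in inflamed and 0.202 ± 0.247 FPKM in desert tumours. H19 (ENSMUSG00000000031, chromosome 7, 142129262 to 142131886), an imprinted non-coding RNA, was at 0.982 ± 0.743 FPKM in inflamed and 1670 ± 1128 FPKM in desert tumours. Of 16750 tested genes, 5197 (31%) were higher and 5221 (31.2%) lower in inflamed tumours by limma, and 6332 did not pass; 11002 had an unadjusted p under 0.05. The groups did not overlap in 8183 tested genes (48.9%), against 0.79% by chance. With rescaling to TPM, which put the median difference of all genes at -0.28 (log2) against -0.0072, 3769 genes were higher and 6989 lower, a higher share of 35.0% against 49.9%; quantile normalization put that median at -0.11. A fold change floor of 2 left 1137 higher and 643 lower. Of the 37 lists tested as sets, 22 were higher and 2 lower with the preset correlation and 0 with an estimated correlation, and 6 of 100 splits of the libraries, the real one included, gave at least as many lists.

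**Figure D1:**
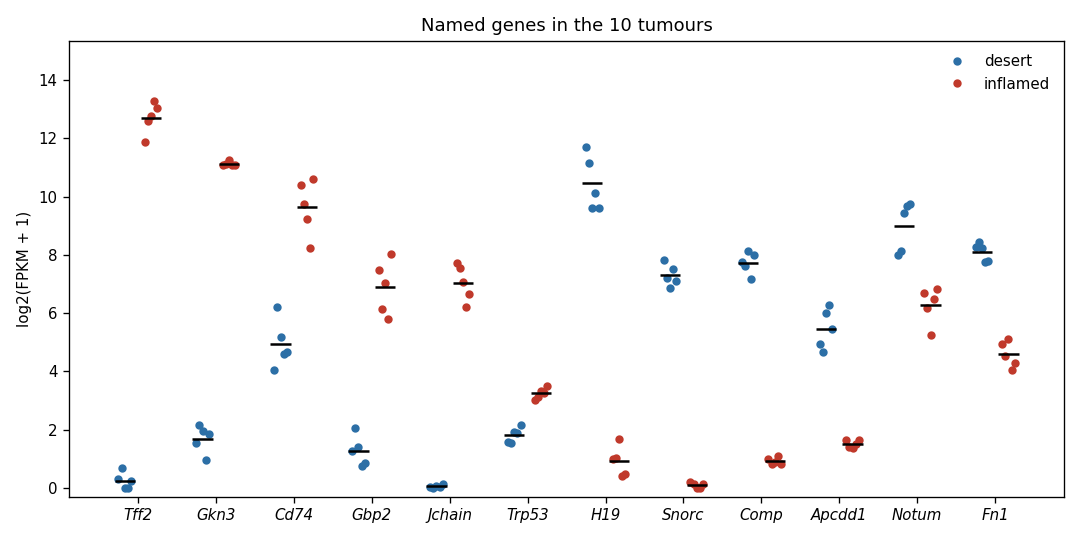
Expression of 12 named genes as log2(FPKM + 1) on the y axis, with 1 point per tumour (5 desert, 5 inflamed) and a line at each group mean. Tff2, Gkn3, Cd74, Gbp2, Jchain and Trp53 were higher in all 5 inflamed tumours, and H19, Snorc, Comp, Apcdd1, Notum and Fn1 in all 5 desert tumours.

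The 12 largest rises were those of Tff2 (log2 difference 12.47, SE 0.24, limma adjusted p = 7.22e-11), Gkn2, Lypd8l, Gkn1, Pgc, Lypd8, Pigr, Dmbt1, Gkn3, Sprr2a3, Mucl3 and Sprr2a2, which was listed at 0 in all 5 desert tumours. Gkn3, a gastrokine, was at 2242 ± 131 FPKM in inflamed and 2.35 ± 0.973 FPKM in desert tumours (SD, n = 5 each). Pigr, the receptor that carries polymeric immunoglobulin across epithelium, was at 880 ± 351 FPKM against 0.0304 ± 0.0305 FPKM. Gkn2 ranged from 800 FPKM in inflamed tumour 1 to 18300 FPKM in inflamed tumour 4. Sprr2a2, Sprr2a3, Lypd8 and Lypd8l belong to families of near-identical copies, and how the authors' counting split such reads was not given. Among the 12 largest falls were those of H19 (fell by 9.54, SE 0.42, limma adjusted p = 2.11e-08), Obp2a, Snorc, Comp, Nptx1, Slc14a1, Igf2, Npy, Siglec15, Col2a1 and Arsi (fell by 5.61). Comp and Col2a1 encode cartilage matrix proteins. Comp was at 0.903 ± 0.169 FPKM in inflamed and 217 ± 53.1 FPKM in desert tumours (SD, n = 5 each). Col2a1 was at 0.0117 ± 0.0053 FPKM in inflamed tumours (SD, n = 5) and at 163.5, 67.3, 20.5, 50.0 and 28.3 FPKM in desert tumours 1 to 5. Igf2, the growth factor gene next to H19, was at 0.108 ± 0.0353 FPKM in inflamed tumours (SD, n = 5) and at 212.7, 74.7, 38.5, 42.9 and 32.7 FPKM in desert tumours 1 to 5.

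Lymphoid and granulocyte lists were higher in inflamed tumours. Of 11 tested T cell markers, 10 rose and Zap70 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00468, adjusted p = 0.572 with an estimated correlation). Cd8a, the coreceptor of cytotoxic T cells, was at 3.49 ± 1.96 FPKM in inflamed and 0.139 ± 0.102 FPKM in desert tumours, and Trbc2 at 7.77 ± 3.76 and 0.149 ± 0.110 FPKM. Zap70, a T cell receptor kinase, was at 2.79 ± 0.990 and 12.1 ± 5.40 FPKM (SD, n = 5 each). All 6 tested cytotoxic and NK cell markers rose (6 adjusted over the list alone; adjusted p = 0.00847, adjusted p = 0.540 with an estimated correlation). The granzyme gene Gzma was at 25.6 ± 16.0 against 0.285 ± 0.248 FPKM and Gzmb at 9.79 ± 5.47 against 0.0859 ± 0.0446 FPKM. The other members of this list of 14 lay below the filter, which genes high in 1 group pass more easily. Among them, the NK cell receptor genes Ncr1 and Klrb1c were at no more than 0.198 and 0.139 FPKM in any tumour. Gzmk was at 0.371 to 1.19 FPKM in inflamed and at no more than 0.134 FPKM in desert tumours. All 5 tested B and plasma cell markers rose (5 adjusted over the list alone; adjusted p = 0.0103, adjusted p = 0.540 with an estimated correlation). Jchain, the joining chain of secreted immunoglobulin, was at 140 ± 56.8 against 0.0402 ± 0.0401 FPKM. The B cell receptor gene Cd79a, chosen after its values were seen, was at 1.75 ± 0.861 against 0.215 ± 0.0426 FPKM (SD, n = 5 each). Below the filter lay both B cell genes such as Ms4a1 and Pax5 and plasma cell genes such as Mzb1 and Tnfrsf17. Of 10 neutrophil markers 9 rose (10 adjusted over the list alone; adjusted p = 0.00359, adjusted p = 0.540 with an estimated correlation). S100a9 was at 81.6, 85.4, 84.8, 5.54 and 12.4 FPKM in inflamed tumours 1 to 5 and at no more than 0.606 FPKM in the desert tumours. Of 10 mast cell markers 5 rose and Gata2 fell (5 and 1 adjusted over the list alone; adjusted p = 0.0297, adjusted p = 0.540 with an estimated correlation), and this call was also lost without inflamed tumour 4 (adjusted p = 0.0571, with 0.00471 to 0.0983 over the alternatives), with a mean FPKM of at least 5, with array quality weights and with voom. Mcpt1, a mucosal mast cell protease, was at 47.7, 54.7, 39.4, 239 and 115 FPKM in inflamed tumours 1 to 5 and listed at 0 in all 5 desert tumours.

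Of 16 macrophage and monocyte markers 7 rose, 0 fell and 9 did not pass limma's test (7 adjusted over the list alone; adjusted p = 0.027, adjusted p = 0.640 with an estimated correlation, and adjusted p = 0.0672 without desert tumour 4, with 0.00157 to 0.0983 over the alternatives). Cd14, part of the endotoxin receptor, was at 57.6 ± 18.6 against 4.66 ± 1.85 FPKM and Spp1 at 119 ± 69.8 against 20.4 ± 8.44 FPKM. The lysozyme gene Lyz2 was at 111 ± 55.9 and 94.6 ± 52.8 FPKM (limma adjusted p = 0.624). The complement gene C1qa, chosen after its values were seen, was at 51.3 ± 26.8 and 29.8 ± 10.1 FPKM (limma adjusted p = 0.154), and was called higher without inflamed tumour 4 (adjusted p = 0.0223, with 0.0126 to 1 over the alternatives). Of 6 dendritic cell markers 3 rose and 2 fell (3 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.739). Irf8 was at 11.0 ± 4.22 against 2.79 ± 0.770 FPKM, and Fscn1, an actin bundling gene, at 6.91 ± 1.70 against 25.2 ± 7.92 FPKM (SD, n = 5 each).

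Antigen presentation, interferon and cytokine lists were higher in inflamed tumours. All 13 MHC class I presentation genes rose (adjusted p = 0.000768, adjusted p = 0.540 with an estimated correlation), as did all 7 tested MHC class II genes (adjusted p = 0.00118, adjusted p = 0.540 with an estimated correlation), with 13 and 7 adjusted over the list alone. Cd74, the invariant chain, was at 932 ± 520 FPKM in inflamed and 34.1 ± 22.7 FPKM in desert tumours, and H2-K1 at 945 ± 337 and 313 ± 140 FPKM. B2m, also in the class I list, lost its call under quantile normalization (0.54, adjusted p = 0.239). Of 14 interferon-gamma response genes 13 rose (13 adjusted over the list alone; adjusted p = 0.000324, adjusted p = 0.540 with an estimated correlation). The guanylate-binding protein gene Gbp2 was at 138 ± 84.0 against 1.54 ± 0.994 FPKM. Of 18 type I interferon response genes 12 rose and Ddx58 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00468, adjusted p = 0.608 with an estimated correlation). Oasl1 was at 59.9 ± 35.1 FPKM in inflamed tumours (SD, n = 5) and at 0.586 to 4.15 FPKM in desert tumours. Of 17 chemokine genes 14 rose (14 adjusted over the list alone; adjusted p = 0.000188, adjusted p = 0.540 with an estimated correlation, and 2.19e-06 to 0.0578 over the alternatives, the highest with a mean FPKM of at least 5). The neutrophil attractant Cxcl5 was at 7.62 to 45.0 FPKM in inflamed tumours and at 0.00566 ± 0.0127 FPKM in desert tumours. Cxcl14 was at 21.7 ± 4.42 and 20.8 ± 1.68 FPKM (limma adjusted p = 0.835). Of 13 inflammatory cytokine genes 12 rose and Il23a fell (12 and 1 adjusted over the list alone; adjusted p = 0.00118, adjusted p = 0.540 with an estimated correlation). Il1b was at 16.5 ± 7.37 against 0.176 ± 0.0796 FPKM. Of 12 immune checkpoint genes 8 rose and Cd276 fell (8 and 1 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.540 with an estimated correlation). Ido1, which degrades tryptophan, was at 21.4, 14.4, 25.7, 17.5 and 126 FPKM in inflamed tumours 1 to 5 and at no more than 0.034 FPKM in desert tumours. Cd276 was at 12.5 ± 2.39 against 20.4 ± 3.90 FPKM (SD, n = 5 each).

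**Figure D2:**
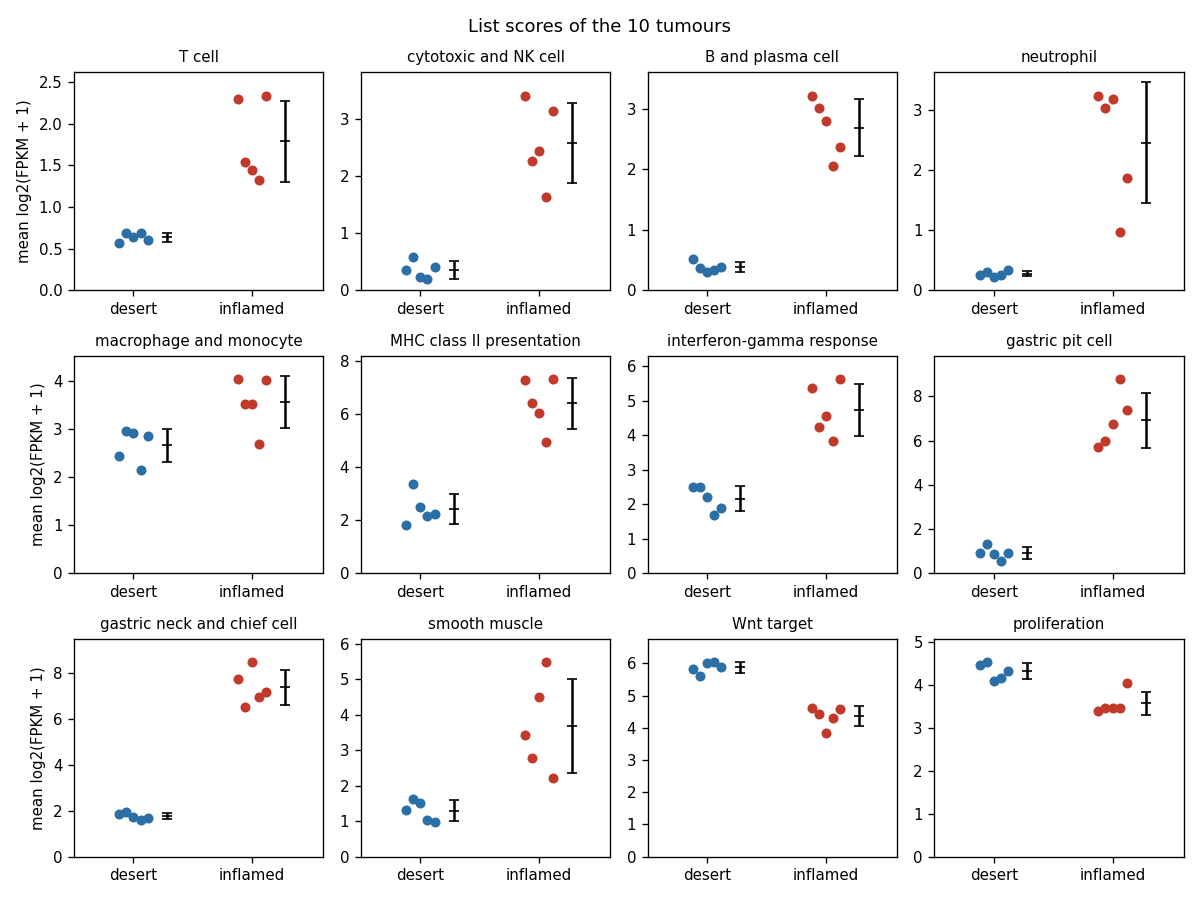
Mean log2(FPKM + 1) over the tested members of 12 fixed lists on the y axis, with 1 point per tumour and the group mean ± SD at the side (n = 5 each). The macrophage and monocyte scores of the groups overlap, the gastric scores lie above all desert tumours in all 5 inflamed tumours, and the Wnt target scores lie below them.

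Epithelial lists were higher in inflamed tumours, and general epithelial genes were also expressed in desert tumours. Of 11 gastric pit cell markers 10 rose (10 adjusted over the list alone; adjusted p = 5.65e-05, adjusted p = 0.540 with an estimated correlation). Of 9 gastric neck and chief cell markers 7 rose and Aqp5 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00137, adjusted p = 0.510 with an estimated correlation). The pepsinogen gene Pgc was at 2532, 813, 6737, 1350 and 743 FPKM in inflamed tumours 1 to 5 and at no more than 1.32 FPKM in desert tumours. Of 6 parietal cell markers 5 rose (5 adjusted over the list alone; adjusted p = 0.0285, adjusted p = 0.540 with an estimated correlation, and 0.00391 to 0.068 over the alternatives, the highest with array quality weights). The proton pump gene Atp4b was at 15.5, 0.197, 104, 81.9 and 16.7 FPKM in inflamed tumours 1 to 5 and at no more than 0.454 FPKM in desert tumours, and it was not called with voom (adjusted p = 0.163, with 2.96e-05 to 0.163 over the alternatives). Of 7 enteroendocrine markers 6 rose (6 adjusted over the list alone; adjusted p = 0.0228, adjusted p = 0.540 with an estimated correlation). Chga was at 21.2, 14.4, 48.6, 6.96 and 4.34 FPKM in inflamed tumours 1 to 5 and at no more than 0.477 FPKM in desert tumours. Of 9 intestinal markers 8 rose and Reg4 fell (8 and 1 adjusted over the list alone; adjusted p = 0.00607, adjusted p = 0.540 with an estimated correlation). Krt20 was at 216 ± 85.1 against 0.117 ± 0.120 FPKM, and Reg4 fell by 5.26 on the log2 scale (limma adjusted p = 1.68e-08). Of 13 pan-epithelial genes 9 rose and Grhl2 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00359, adjusted p = 0.540 with an estimated correlation). Krt8 was at 1543 ± 633 FPKM in inflamed and 510 ± 46.6 FPKM in desert tumours. Epcam, chosen after its values were seen, was at 368 ± 35.6 and 305 ± 77.3 FPKM (limma adjusted p = 0.124), and was called higher without desert tumour 1 (adjusted p = 0.0107, with 0.0107 to 1 over the alternatives). Of 10 squamous forestomach markers 3 rose (3 adjusted over the list alone; adjusted p = 0.0408, adjusted p = 0.608 with an estimated correlation), a call also lost in 6 of 25 alternatives, among them those without desert tumour 1, 4 or 5 (adjusted p = 0.0582, 0.0574 and 0.053, with 0.00168 to 0.332 over the alternatives). Krt13 was at 154 FPKM in inflamed tumour 4 and at no more than 4.70 FPKM in the other inflamed tumours. Its difference was not called (limma adjusted p = 0.0977) but was called without inflamed tumour 4 (1.04, adjusted p = 0.0321, with 0.00194 to 0.833 over the alternatives).

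Of 10 smooth muscle markers 7 rose (7 adjusted over the list alone; adjusted p = 0.0161, adjusted p = 0.608 with an estimated correlation), with Actg2 at 53.1, 30.5, 111, 234 and 13.5 FPKM in inflamed tumours 1 to 5 and at no more than 1.59 FPKM in desert tumours. Fibroblast and matrix genes went both ways (7 of 15 rose and 2 fell, and 8 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.138). Dcn, a matrix proteoglycan, was at 36.6 ± 13.3 against 6.79 ± 3.95 FPKM, and Fbln1 at 11.3 ± 3.44 against 108 ± 25.9 FPKM (SD, n = 5 each). Of 12 endothelial markers 5 rose and Cldn5 fell (5 and 1 adjusted over the list alone; adjusted p = 0.113), and the list was called without inflamed tumour 4 (adjusted p = 0.0225, with 0.0225 to 0.18 over the alternatives). Cldn5 was not called in 12 of 25 alternatives, among them those without inflamed tumour 2, 4 or 5 or desert tumour 2, 4 or 5 (limma adjusted p = 0.0549, 0.0721, 0.0836, 0.0628, 0.0601 and 0.0635, with 0.0151 to 1 over the alternatives). Of 8 skeletal muscle genes Mylpf fell (0 adjusted over the list alone; adjusted p = 0.33), but not without desert tumour 2 (limma adjusted p = 0.0645, with 0.00498 to 0.825 over the alternatives). Acta1, skeletal actin, was at 41.6 and 106 FPKM in desert tumours 2 and 3 and at no more than 0.811 FPKM in the other 8 libraries. Tnni2, a fast muscle troponin gene of the same list, went the other way. It was at 9.14 to 38.0 FPKM in inflamed tumours and at 1.48, 7.08, 38.0, 1.26 and 1.37 FPKM in desert tumours 1 to 5 (log2 difference 1.67, limma adjusted p = 0.0719). It was called higher without desert tumour 3 (2.39, limma adjusted p = 0.00144, with 0.000308 to 1 over the alternatives). Of 5 erythroid genes Hba-a2 and Alas2 fell (0 adjusted over the list alone; adjusted p = 0.191). Alas2 was not called without inflamed tumour 1, 2 or 4 or desert tumour 1, 3 or 4 (limma adjusted p = 0.0875, 0.0768, 0.0757, 0.0791, 0.0521 and 0.0708, with 0.00934 to 1 over the alternatives). Hba-a2 was not called with the tumour number as a block (limma adjusted p = 0.0542) or with chromosome medians removed (0.0593). It was also not called without desert tumours 2 and 3 together (0.0602, with 0.00374 to 1 over the alternatives). The haemoglobin genes Hba-a1 and Hbb-bs did not pass (log2 differences -1.67 and -1.83, limma adjusted p = 0.0556 and 0.0758). Without inflamed tumour 3 or 5, Hba-a1 was called lower (limma adjusted p = 0.0164 and 0.0356, with 0.0164 to 0.979 over the alternatives), as was Hbb-bs (0.0208 and 0.049, with 0.0208 to 0.956). Both were also called lower after rescaling to TPM (limma adjusted p = 0.0276 and 0.0428). Haemoglobin genes have near-identical copies, so reads can be split between them. Lists with fewer than 5 tested members had no set test: 2 of 4 regulatory T cell, 2 of 4 adipocyte, 1 of 2 pancreatic acinar and 1 of 3 hepatocyte genes were higher (Ikzf2 and Tnfrsf4, Fabp4 and Cidec, Clps, and Apoa1), and of 4 nerve and glia genes S100b and Ret were higher and Uchl1 lower. Rescaling to TPM ended the calls of Tnfrsf4, Fabp4 and S100b (limma adjusted p = 0.108, 0.0835 and 0.0664). Tnfrsf4 also lost its call under quantile normalization (limma adjusted p = 0.0924) and without inflamed tumour 1 or 5 (0.0511 and 0.0518, with 0.00137 to 1 over the alternatives). Fabp4 lost it without inflamed tumour 3 or 4 or desert tumour 5 (limma adjusted p = 0.0544, 0.0512 and 0.0548, with 0.000366 to 1 over the alternatives). S100b lost it with the tumour number as a block (limma adjusted p = 0.0546). It also lost it without inflamed tumour 1 or desert tumour 1, 2 or 4 (limma adjusted p = 0.054, 0.0579, 0.0547 and 0.0541, with 0.00565 to 1 over the alternatives). Clps, a pancreatic colipase gene, was at 602, 10.8, 1766, 107 and 88.4 FPKM in inflamed tumours 1 to 5 and at 1.52 to 9.07 FPKM in desert tumours. Cela1, the other tested acinar gene, was at 128.5 ± 44.7 and 121 ± 34.0 FPKM (SD, n = 5 each, limma adjusted p = 0.866). Alb was at 1.59 to 7.01 FPKM in inflamed tumours and at 41.3, 52.3, 24.7, 3.05 and 0.608 FPKM in desert tumours 1 to 5. It was not called (limma adjusted p = 0.197), but was called lower without desert tumour 5 (adjusted p = 0.0207, with 0.0207 to 1 over the alternatives).

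Wnt targets and proliferation genes were lower in inflamed tumours. Of 16 Wnt targets 13 fell, 2 rose and Sp5 did not pass (13 and 2 adjusted over the list alone; adjusted p = 0.00066, adjusted p = 0.540 with an estimated correlation). The secreted Wnt inhibitor gene Notum was at 82.4 ± 29.7 FPKM in inflamed and 580 ± 294 FPKM in desert tumours, Nkd1 at 78.6 ± 30.4 and 271 ± 50.7 FPKM, and Apcdd1 at 1.87 ± 0.262 and 47.0 ± 21.8 FPKM (SD, n = 5 each). The 2 that rose, Myc and Cd44, differed by 0.78 and 1.40 on the log2 scale (limma adjusted p = 0.00168 and 9.34e-05). Of 20 proliferation genes 15 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 0.00131, adjusted p = 0.572 with an estimated correlation). Top2a, a topoisomerase of dividing cells, was at 25.2 ± 9.04 against 58.6 ± 10.1 FPKM, and the mitotic kinase gene Plk1, the member that rose, at 76.5 ± 4.05 against 36.4 ± 6.81 FPKM. The list scores of both differed with the smallest exact p the design allows (0.00794, adjusted 0.0113). Lists that the set test did not call, such as the p53 target and ribosome biogenesis lists, reached the same exact p, so it is not particular to these lists.

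Of 9 mitochondrially encoded genes 5 rose (6 adjusted over the list alone; adjusted p = 0.0439, adjusted p = 0.608 with an estimated correlation). The call was lost in 12 of 25 other alternatives. Among these were quantile normalization (adjusted p = 0.836), both other pseudocounts, the mean FPKM of at least 5, array quality weights, and the fits without inflamed tumour 4 or 5 or desert tumour 4 or 5 (adjusted p = 0.0717, 0.0576, 0.0689 and 0.0588, with 0.0158 to 0.836 over the alternatives). Of 15 p53 targets 7 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.243). The death receptor gene Fas was at 6.05 ± 1.77 against 0.257 ± 0.0987 FPKM. Of 10 mesenchymal transition genes Zeb2 and Snai2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.975). The matrix gene Fn1 was at 23.9 ± 7.59 against 276 ± 57.0 FPKM and the transcription factor gene Twist1 at 0.131 ± 0.102 against 8.56 ± 5.55 FPKM. The median of the list's differences (0.12) and the direction of the set test were upward, the mean (-0.46) was downward, and the score was lower by exact permutation (adjusted p = 0.021). Of 12 TGF-beta pathway genes 6 rose and 3 fell (6 and 4 adjusted over the list alone; adjusted p = 0.525). Tgfbi was at 36.5 ± 10.2 against 3.16 ± 1.80 FPKM and Tgfb3 at 3.39 ± 0.969 against 33.4 ± 13.1 FPKM. Of 13 ribosome biogenesis genes 7 fell and Rrp9 rose (7 and 1 adjusted over the list alone; adjusted p = 0.164), and the list was called lower with chromosome medians removed (adjusted p = 0.0288, with 0.0288 to 0.301 over the alternatives). Rescaling to TPM put the median difference of all tested genes at -0.28, and the Rrp9 difference of 0.19 turned to -0.080 there. The Rrp9 difference turned to -0.035 with chromosome medians removed. It was called in none of the fits with 1 tumour left out except the one without inflamed tumour 4 (limma adjusted p = 0.0517 to 0.105 in the others, with 0.0175 to 1 over the alternatives). Of 17 oxidative phosphorylation genes 8 rose and 3 fell (8 and 3 adjusted over the list alone; adjusted p = 0.165), and the mean of that list was -0.03 after rescaling to TPM against 0.27, or 0.25 relative to all genes. Of 11 immediate-early and heat shock genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; adjusted p = 0.288), and of 16 hypoxia and glycolysis genes Pdk1 rose and Bnip3 and P4ha1 fell (0 and 1 adjusted over the list alone; adjusted p = 0.753), with a mean of -0.07 that turned to 0.0077 with chromosome medians removed. Pdk1 was not called after rescaling to TPM (limma adjusted p = 0.145, with 0.0016 to 1 over the alternatives), and Bnip3 was not called without inflamed tumour 2 or 5 (0.0515 and 0.0595, with 0.00463 to 1 over the alternatives). The sex-linked list was not called (4 of 5 rose, 4 adjusted over the list alone; adjusted p = 0.106, and 0.00404 without inflamed tumour 3, with 0.00368 to 0.63 over the alternatives). Eif2s3y, on the Y chromosome, was at 18.7, 16.6, 18.1 and 13.8 FPKM in inflamed tumours 1, 2, 4 and 5 and listed at 0 in inflamed tumour 3 and all 5 desert tumours. By exact permutation test 31 of the 37 list scores differed after adjustment.

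**Figure D3:**
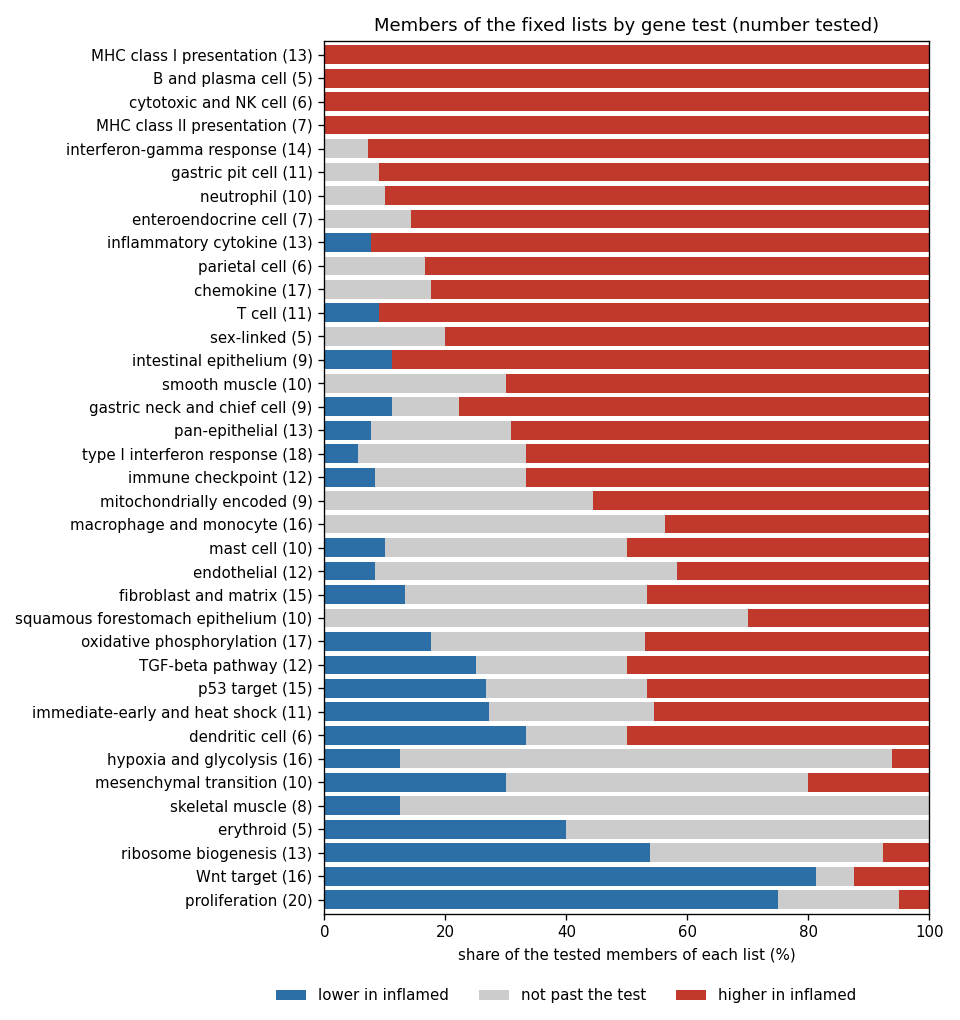
Share of the tested members of each of 37 fixed lists (x axis, percent) that were higher, lower or not past limma's test in inflamed tumours, with the number tested in brackets. All 13 MHC class I genes were higher, and 15 of 20 proliferation genes were lower.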

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

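Of 384 groups of 5 values (list scores, library measures and named genes on the log2 scale), 35 held a tumour far from the other 4, against about 19 by chance, since chance marks about 1 group in 20. The test of inflamed tumours 3 and 4 left out was chosen after these values were seen. A gene listed at 0 in the other 4 tumours of a group is flagged by any value above 0. Tff1 in desert tumour 4 and Cxcl5 in desert tumour 5 were flagged this way, and the chance rate does not describe such groups.

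Inflamed tumour 4 stood apart most often. Its squamous forestomach score of 4.65 lay above the other inflamed tumours, and its chemokine score of 1.93, TGF-beta pathway score of 2.77 and ribosome biogenesis score of 3.97 lay below them; mitochondrial genes took 3.71% of its reads. Tff1 was at 37.8 FPKM and Krt10 at 68.2 FPKM there, Fos at 89.0 FPKM and Egr1 at 19.3 FPKM, all above the other inflamed tumours. Cd14 at 25.0 FPKM, Cxcl5 at 7.62 FPKM, Cxcl14 at 14.3 FPKM and Il1b at 4.79 FPKM lay below them. Inflamed tumour 5 stood apart with a proliferation score of 4.05, Top2a at 41.1 FPKM and Ido1 at 126 FPKM. Inflamed tumour 3 had low Wif1 at 5.94 FPKM, a sex-linked score of 1.13, Xist at 48.9 FPKM, and Eif2s3y and Ddx3y at 0. Inflamed tumour 1 had Arsi at 1.22 FPKM.

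Among desert tumours, tumour 2 had Gkn2 at 3.88 FPKM, Pgc at 1.32 FPKM, Lypd8l at 0.421 FPKM and Pmaip1 at 1.23 FPKM. Desert tumour 4 had Zap70 at 21.6 FPKM, Clic6 at 2.79 FPKM and Tff1 at 0.0748 FPKM. Desert tumour 1 had Pou2af1 at 0.358 FPKM, Apoa1 at 0.211 FPKM and a library total behind its FPKM of 1.04 times the recovered reads. Desert tumour 3 had Npm1 at 129.5 FPKM, and desert tumour 5 had Egr1 at 0.670 FPKM and Cxcl5 at 0.0283 FPKM.

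Gastric genes were higher in inflamed tumours, and a candidate explanation is corpus mucosa around the tumours. These lists hold markers of normal stomach, and Atp4b reached 104 and 81.9 FPKM in inflamed tumours 3 and 4. In inflamed tumour 2 Atp4b was at 0.197 FPKM, yet the pit score was 5.99 and the neck and chief score 6.52, against at most 1.33 and 1.95 in desert tumours. Among inflamed tumours the neck and chief score, like the parietal score, was lowest in tumour 2 and highest in tumour 3, whereas the pit score was lowest in tumour 1. A single tumour with little parietal signal cannot decide the question. If mucosa were the source, the 17 gastric pit, neck and chief genes called higher should follow the parietal signal. Without inflamed tumours 3 and 4, the parietal list mean went from 2.44 to 1.68, and the median difference of the 17 genes from 6.43 to 6.12, with all 17 still called. The parietal signal fell by less than the bound of 1 set for the test and no normal mucosa was measured, so the explanation stays open, as does a biological difference between the tumour models, which was not tested.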

How the results depend on the processing

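Voom, the 3 sets of libraries left out and the removal of chromosome medians were chosen after the data had been examined; all other settings were planned. Over the 10 single libraries left out, genes higher in inflamed tumours numbered 4829 to 5225 and genes lower 4911 to 5134, with 0 calls in the opposite direction; higher lists numbered 19 to 23, lower lists 2, list scores past the threshold 28 to 33, the Apc difference was 0.37 to 0.55, Trp53 1.36 to 1.52 and Tff1 1.71 to 2.07 (called without inflamed tumour 1, adjusted p = 0.0472; without inflamed tumour 4, and with the filter at 5, it was not tested). A mean FPKM of at least 5 tested fewer genes and gave 2784 higher, 3070 lower and 10 higher lists. A fold change floor of 2, a stricter test, gave 1137 and 643. Without inflamed tumours 3 and 4 there were 4852 and 4680, and without desert tumours 2 and 3 there were 4454 and 4572. Inflamed tumour 3, the only inflamed one without Y-linked reads, against the 5 desert tumours gave 3170 and 2641, with fewer samples and that tumour assumed to vary like the others; there Xist turned to 4.39, against -0.11. With an estimated correlation 0 lists were higher and 0 lower (22 and 2 with the preset); voom gave 21 and 2. Apc was not called after TPM rescaling (0.25), with the floor of 2 (0.47), without inflamed tumours 3 and 4 (0.35), without desert tumours 2 and 3 (0.47) or in the tumours without Y-linked reads (0.81; adjusted p 0.0609 to 1 over these). Tff1 was called with pseudocounts of 0.1 (3.98) and 0.01 (6.68), TPM (2.74), voom (4.92) and without inflamed tumours 3 and 4 (0.76). That last fit kept the filter over all 10 libraries and left out inflamed tumour 4, where Tff1 was at 37.8 FPKM. In the other inflamed tumours Tff1 was at 0.242 to 1.56 FPKM. Its difference in the tumours without Y-linked reads was 1.02. The cause of these calls was not tested. Voom called 5221 higher and 5787 lower, 4545 and 5002 of them shared. Rrp9 turned to -0.080 with TPM, where the median of all tested genes was -0.28, and to -0.035 with chromosome medians removed, against 0.19. Of 4493 values of named genes, 4247 kept their side of the threshold, 182 lost it, 61 gained it and 3 reversed; of 950 list values, 890, 52, 8 and 0. Tumours with the same number did not deviate together (correlations -0.0737 to 0.0763, 2 of 10 libraries closest to their own number). With the number as a replicate block, 4958 genes were higher and 4967 lower, and the mitochondrially encoded list was not called (camera adjusted p = 0.0505). Of 174 named genes, 5 lost their call with the block and 2 gained one. At 14148147 reads or more per library, genes under the filter were not tested.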

Other observations

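The test of dilution by other tissue and that of copy number were chosen after the results had been seen, as were the Hox genes and the removal of chromosome medians. Of 39 Hox genes, which pattern the body axis, 13 passed the filter, and by limma 12 of these were lower in inflamed tumours and 0 higher. The set was picked because its fall had been seen, and genes high in 1 group pass the filter more easily, so the count is a description without a test of the set. Hoxc10 was listed at 0 in all inflamed tumours and at 16.3 ± 1.76 FPKM in desert tumours, and Hoxc9 at 0 and 9.48 ± 0.849 FPKM (SD, n = 5). Hoxb4 was the tested member that did not pass (0.750 ± 0.292 and 1.20 ± 0.572 FPKM), and it was called lower after rescaling to TPM (limma adjusted p = 0.0421, with 0.0292 to 1 over the alternatives).

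Inflamed tumours 1, 2, 4 and 5 expressed the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which were listed at 0 in inflamed tumour 3 and the desert tumours. Xist was at 48.9 FPKM in inflamed tumour 3, at 0.912 to 2.21 FPKM in the desert tumours and at no more than 0.0265 FPKM in the other inflamed tumours. The desert tumours thus matched inflamed tumour 3 in the Y-linked genes, whereas their Xist values lay between that tumour and the other inflamed tumours. The sex of the grafted cells and of the hosts was not given in the sources used here.

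Whether chance can be excluded was asked with 100 of the 126 splits of the 10 libraries into 5 and 5, the real split included. For the count of genes, 1 split, the real one, gave as many as the real 10418, and the highest of the others was 1. For the count of lists called with the preset correlation, 6 of 100 splits gave at least the real 24, and the highest other gave 27. Every split but the real one mixes the tumour types unevenly and so keeps part of the real difference. That difference also widens the spread within the mixed groups, which lowers their gene counts. The gene count was thus particular to the real split among those drawn, but the others do not show how many genes chance alone would call. Nor can the splits decide whether chance alone would give the list count, and chance was not excluded for it.

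The Wnt targets were lower in the tumours with floxed Apc, whose loss is known to raise Wnt target expression, but the genotype of the grafted cells at Apc and other Wnt pathway genes was not given in the sources used here. Shifts of whole chromosomes were too small to account for the fall. With chromosome medians removed the mean of the Wnt list went from -1.52 to -1.33, and 13 of the 16 targets were still lower. Shifts of only a part of a chromosome are not taken out by this step and were not tested. Dilution of tumour cells by other tissue in inflamed tumours may contribute. The Wnt median lay further down than that of the proliferation genes, by -0.719 on the log2 scale (-1.53 against -0.81, permutation p = 0.0091 across genes), but cells of other tissue divide too, and no measure of the share of tumour cells was at hand, so dilution and a difference between the tumour models cannot be told apart.

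Medians of many chromosomes were shifted between the groups, some of them mainly through 1 part of the chromosome. Over 12840 protein-coding genes, the median log2 difference was 0.41 on chromosome 5, 0.35 on chromosome 17 and 0.30 on chromosome 4, and -0.43 on chromosome 18, -0.38 on chromosome 15 and -0.33 on chromosome 7. GC content and gene length do not account for it: the SD of the 19 autosome medians was 0.262, and 0.265 after both were regressed out (values for 99.86% of the genes), against at most 0.0585 in 100 random assignments of genes to chromosomes. A difference in copy number between the tumour models is a candidate explanation, since medians of the proximal and distal parts of the autosomes went together (Pearson r = 0.741, permutation p = 0.00035; Spearman rho = 0.758, permutation p = 0.00028; r = 0.813 without the 2 farthest chromosomes), although several chromosomes were shifted mainly in 1 part: chromosomes 7 (proximal -0.61, distal -0.0049), 8 (-0.33, -0.0096), 10 (-0.29, -0.0042) and 9 (0.02, 0.45). Chromosome medians also varied more among desert tumours (mean SD 0.0814, larger on 17 of 19 autosomes) than among inflamed tumours (0.0266); DNA was not measured, and strain and other differences between the models stay open.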
